A study of Homo sapiens with 5 samples.

How the data were processed

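RNA from SW620 cells was prepared as stranded poly(A) libraries with the TruSeq Stranded mRNA kit, per the labels' protocols. The authors deposited a single table of raw counts per gene symbol for 5 libraries, made by aligning reads with STAR, per the labels' protocols. The submitters' processing notes list CASAVA 1.8.2 and STAR 2.5.2b, and DESeq2 1.24.0 for the authors' own comparison, which is not used here. The genome build is given in 2 ways, as hg19 in the submitters' processing notes and as GRCh38 in the labels' extraction protocol, so no coordinates were taken from the authors' side. The counting program and its strand setting are not given in the sources used here, and without strand, reads of overlapping and antisense genes cannot be told apart. Reads shared between paralogs or with pseudogenes, as for ribosomal proteins, are likewise uncertain.

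The table held 25435 rows, of which 92 were spike-in rows at 0 in every library and were left out, and it held no mitochondrially encoded transcripts. Of the 25343 gene rows, 6886 had no read in any library. Each column was matched to a library by its name, and groups were taken from the titles. The labels' 2 further processing steps, normalisation and enrichment with Hallmark gene sets, were replaced by the tests below, since the Hallmark sets are not used here.

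Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 13604 genes, scaled by TMM and tested with glmQLFit and glmQLFTest for pos against neg, two-sided, with Benjamini-Hochberg adjustment at 0.05. SE is the log2 fold change divided by the square root of the F statistic. CPM values are TMM-normalised, and for correlations and library ratios log2 CPM had a prior count of 2. No pair of libraries of a group agreed within sampling noise, since the chi-square per degree of freedom of neg pairs was 6.31 to 23.4 and that of the pos pair 158.

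Before the data were examined, 33 gene lists were written by hand from general knowledge, and the 31 with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01. The mitochondrially encoded list had 0 tested members, and the erythroid and hepatocyte list had 1. The genes named were also fixed by rule before the data were examined. They were MUC1, the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 CPM and no overlap between groups, 12 stem cell and pathway genes whatever their p, the 4 members with the smallest p in the direction of each called list, and 2 of every other list with called members. Some genes that these rules pick are not reported here. Histone genes and pseudogenes were not named.

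Alternatives planned before the data were examined were DESeq2 1.42.0, limma-voom, DESeq2 size factors, upper quartile scaling, library size only, no filter, a filter of 5 CPM in 2 libraries, the replicate number as a block, each library left out, stricter thresholds, glmTreat at 1.2-fold, and for lists an estimated correlation, fry and fgsea 1.28.0. After the data were seen, fits were added that remove each library's trend of log2 CPM on transcript length (lowess, span 0.3), or on length and GC content, as offsets, that weight libraries by quality in limma-voom, and that combine length removal with leaving out either pos library. Transcript lengths were those of the canonical transcript in GENCODE 44 (GRCh38), with older symbols matched through RefSeq synonyms, and 96.9% of tested genes had one. Where a pos library was left out, the lone pos library was assumed to vary like the neg libraries. The pos pair differed more than neg pairs did (chi-square per degree of freedom 158 against 6.31 to 23.4). Calls in those fits therefore measure a single library and not the group.

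The edgeR step was tested on simulated counts for pos against neg over 13604 genes with the real means, library sizes and spread. It recovered 57 of 100 genes changed 4-fold and 2 of 100 changed 2-fold, and called 1 unchanged gene. With the real length trend added, 24 and 0 were recovered and camera called 3 lists (ribosomal proteins, oxidative phosphorylation and mitochondrial ribosome). Once the trend was removed, 54 and 2 were recovered and 0 lists called. The trend was added and removed with the same smoother, on a spread that already held it, and genes were drawn independently. Each gene was given the same spread in neg and pos, although the real pos pair differed more than neg pairs did. These counts therefore cannot say how well the trend is removed from the real libraries. Nor can they say how often camera miscalls lists of correlated genes or edgeR calls unchanged genes where pos varies more than neg. At the smaller spread left after removal of the trend, 82 and 27 were recovered and 6 unchanged genes called. At totals of 10888704 to 14137678 counts, 3 counts were equal to 0.189 to 0.316 CPM. Reads were not marked by molecular identifiers as far as the labels say, so intervals and floors cover counting error only.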

Results

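Gene expression was measured by stranded mRNA sequencing in 5 libraries of SW620, a human colon carcinoma cell line that here carried a tetracycline-inducible short hairpin RNA (shRNA) against MUC1. MUC1 encodes a transmembrane mucin, and the series title places its C-terminal subunit, MUC1-C, in the context of stem cell properties in colitis and colorectal cancer. The labels call 3 libraries neg (replicates 1, 2 and 3) and 2 libraries pos (replicates 1 and 3). They say that cells received vehicle or doxycycline, the drug that switches on a tetracycline-inducible shRNA, but not which name stands for which. The reading of neg as vehicle and pos as doxycycline is not written in them, so the names neg and pos are kept. Cells were cultured in triplicate per the labels, and nothing further is said about how the libraries of a group relate. A total of 13174867, 14137678 and 10888704 reads were counted in genes in neg replicates 1, 2 and 3, against 12190025 and 13470767 in pos replicates 1 and 3.

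The comparison of pos with neg asks how the transcriptome of these cells differs between the groups under these names. It shows the cells with the MUC1 shRNA switched on only if pos stands for doxycycline, which the labels do not state. MUC1 itself was lower in both pos libraries, with 27 and 13 reads in replicates 1 and 3 against 176, 252 and 218 in the neg libraries. Its normalised level was 1.78 ± 0.576 CPM (counts scaled to library size; SD, n = 2) against 15.2 ± 2.66 (SD, n = 3), an 8.42-fold fall (log2 fold change -3.07, SE 0.34, edgeR quasi-likelihood adjusted p = 0.0270). The exact Poisson 95% intervals, which cover counting error only, ran from 1.44 to 3.18 CPM in pos replicate 1 and from 0.730 to 2.34 CPM in pos replicate 3, below the lowest neg interval of 10.6 to 14.3 CPM. A fall of the shRNA's target in pos argues against the reverse reading, with neg as doxycycline, though this is read from 1 gene. Without neg replicates 1, 2 and 3 in turn the edgeR adjusted p of MUC1 was 0.178, 0.217 and 0.212, at log2 fold changes of -3.21, -3.05 and -2.97. MUC1 lies on chromosome 1 from 155185824 to 155192916 on the minus strand (GRCh38, GENCODE 44). No library with doxycycline and a control shRNA was analysed here, so if pos stands for doxycycline the comparison holds MUC1 silencing and any effect of the drug together.

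In set tests with a preset inter-gene correlation of 0.01, the lists of endoplasmic reticulum (ER) chaperone genes, amino acid stress genes driven by the transcription factor ATF4 and hypoxia-responsive genes were lower in pos than in neg, and those of DNA replication, mitosis, ribosomal protein and oxidative phosphorylation genes were higher. With the correlation estimated from the data 0 of 31 lists passed. That form of the test also uses only the residual degrees of freedom of the 5 libraries, so its p can rise without correlation between genes. The list of mesenchymal genes had an estimated correlation of -0.00953, below 0.01, yet its unadjusted camera p was 0.0514 against 0.00378. Calls lost with an estimated correlation therefore cannot be laid to correlation alone. The other called lists had estimated correlations above the preset, from 0.0528 for ER chaperones to 0.990 for ribosomal proteins. Their p at the preset can therefore be too small. Without pos replicate 1 the hypoxia call ended (median log2 fold change -0.43 against -0.54) unless the length trend was removed as well. The chaperone HSPA5 fell from 2213 ± 189 to 623 ± 85.7 CPM and the tryptophanyl-tRNA synthetase gene WARS from 434 ± 42.3 to 81.0 ± 5.49 CPM (SD, n = 3 neg and 2 pos, as for all group values below). The ribonucleotide reductase subunit gene RRM2 rose from 25.6 ± 0.968 to 75.5 ± 5.51 CPM, and the stem cell transcription factor gene SOX2 from 18.3 ± 0.253 to 63.7 ± 4.98 CPM. The intestinal stem cell receptor gene LGR5 also rose, from 2.46 ± 0.726 to 11.9 ± 8.15 CPM, with 17.6 CPM in pos replicate 1 and 6.11 in pos replicate 3.

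**Figure D1:**
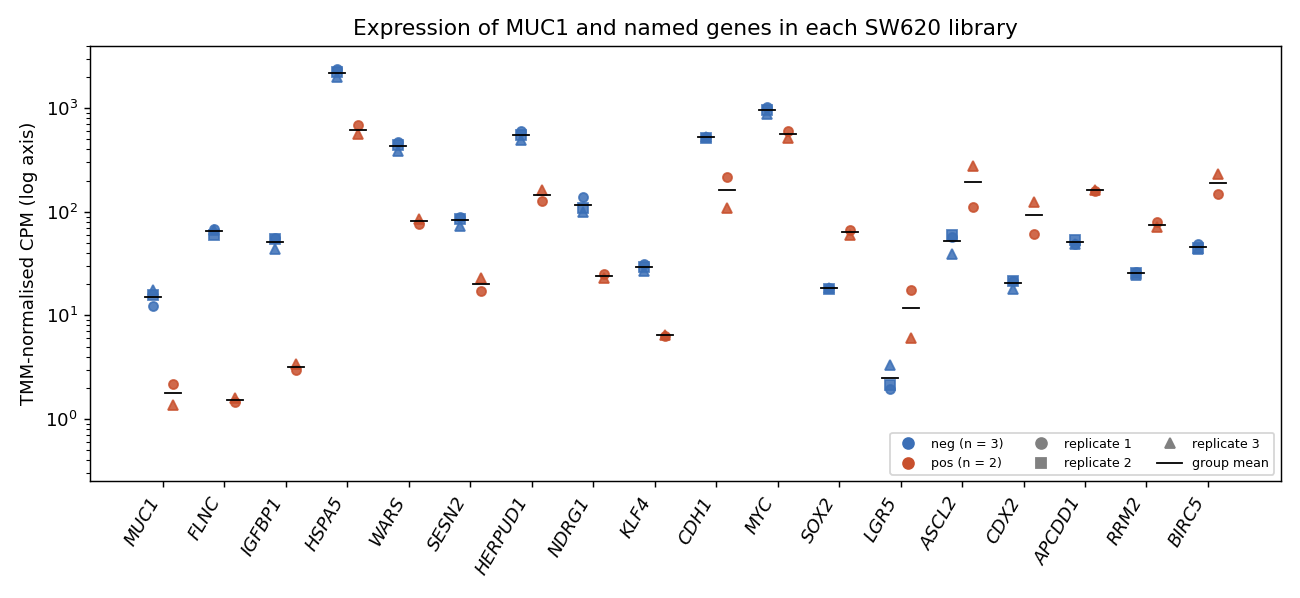
TMM-normalised CPM (log axis) of MUC1 and 17 other genes in each of the 3 neg (blue) and 2 pos (orange) libraries; marker shape gives the replicate number and black lines the group means. MUC1 lies at 2.18 and 1.37 CPM in pos replicates 1 and 3 against 12.3 to 17.5 CPM in the neg libraries, and LGR5, ASCL2, CDX2 and CDH1 differ visibly between the pos libraries.

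Of 13604 genes tested, 1251 passed an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 689 higher and 562 lower in pos, and 1148 of these differed at least 2-fold. With library size as the only scaling, which moved the median log2 fold change of all tested genes from -0.05 to -0.41, the split became 148 higher and 458 lower. The groups did not overlap in CPM for 56.0% of tested genes, where chance gives 20% for a single gene. Genes moved together across the 5 libraries, with 72.0% of variance on the first principal component. The share therefore cannot be tested against 20%. Library traits that set both pos libraries apart from neg, given below, can also raise it. Leaving out neg replicate 1, 2 or 3 left 0 genes past the threshold in edgeR, with 3033, 2510 and 2607 genes at an unadjusted p under 0.05 and 1315, 949 and 850 calls by DESeq2. Leaving out pos replicate 1 or 3 left a lone pos library with its spread taken from neg, so calls from those fits are not counted here. DESeq2 on all 5 libraries called 3042 genes, with 1250 of them shared with the 1251.

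The 2 pos libraries stood apart from each other as well as from neg. Their log2 CPM correlated at Pearson r = 0.912 across genes, which are not independent replicates, against 0.983 to 0.993 among neg pairs. Short transcripts were over-represented in pos replicate 3, where the median log2 ratio to the neg mean was 1.19 in the shortest of 5 equal groups of transcripts and -1.26 in the longest. In pos replicate 1 the same values were 0.37 and -0.26. Ribosomal protein genes took 28.9% of reads in pos replicate 3 and 16.3% in pos replicate 1, against 8.96% to 10.8% in neg. Fewer genes were detected in pos, 14452 and 15530 against 16832 to 17054, and genes with exactly 1 read numbered 143 in pos replicate 1 and 580 in pos replicate 3 against 1118 to 1187 in neg. The median transcript of genes called higher was 1456 nt long, that of genes called lower 4797.5 nt and that of all tested genes 3252 nt. With each library's length trend removed, a step chosen after the data were seen, 1888 genes passed, of which 869 were shared with the 1251 in the same direction.

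**Figure D2:**
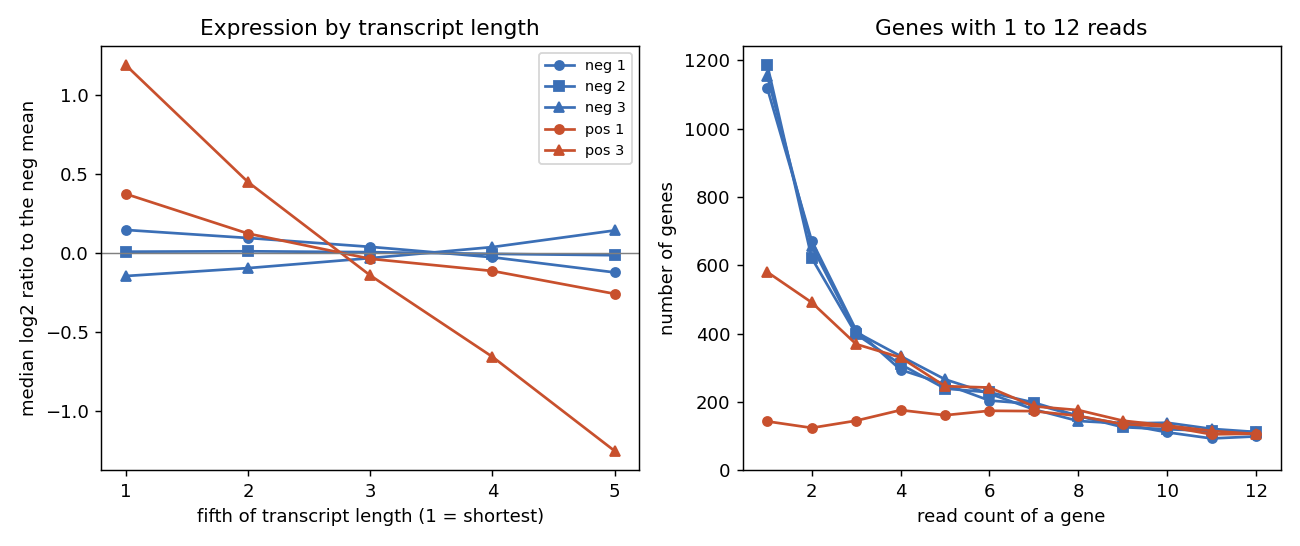
Left, median log2 ratio of each library to the mean of the neg libraries in 5 equal groups of genes ordered by transcript length. Right, number of genes with each read count from 1 to 12; pos replicate 3 falls from 1.19 to -1.26 from the shortest to the longest transcripts, and pos replicate 1 has 143 genes with 1 read against at least 1118 in each neg library.

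ER chaperone and ER quality control genes were lower as a group. Of 26 tested members 12 fell and none rose (20 fell when adjusted over the list alone), with a median log2 fold change of -1.29 and a camera adjusted p of 6.7e-11, which was adjusted p = 0.345 with an estimated correlation. HSPA5 (log2 fold change -1.83, SE 0.23), the ER-stress-induced HERPUD1 (-1.92, SE 0.23), the ER chaperone gene HYOU1 (-1.78, SE 0.20) and the ER ubiquitin ligase gene SYVN1 (-1.26, SE 0.18) had the smallest p among them. The median was -1.23 without pos replicate 3, -1.33 without pos replicate 1 and -1.39 with the length trend removed.

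The integrated stress response, the ATF4 program that raises amino acid synthesis and tRNA charging genes, was lower too. Of 40 members 12 fell and none rose (26 fell when adjusted over the list alone), at a median of -0.89 and a camera adjusted p of 2.3e-10, or adjusted p = 0.355 with an estimated correlation. WARS fell by 2.42 on the log2 scale (SE 0.21), the stress-induced mTORC1 inhibitor SESN2 by 2.04 (SE 0.23), the ATF4 partner CEBPG by 1.62 (SE 0.25) and the angiogenic factor VEGFA by 1.57 (SE 0.19). The median was -1.02 with the length trend removed, and -1.03 and -0.88 without pos replicates 3 and 1.

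Of 34 hypoxia and glycolysis genes 8 fell and none rose (15 fell and 1 rose when adjusted over the list alone). The median was -0.54 and the camera adjusted p 0.000362, or adjusted p = 0.456 with an estimated correlation. The examples were NDRG1, from 115 ± 19.9 to 24.2 ± 1.53 CPM, the MYC antagonist gene MXI1, from 51.6 ± 2.47 to 16.0 ± 0.713 CPM, the oxygen sensor EGLN3, from 23.8 ± 3.20 to 7.08 ± 1.32 CPM, and VEGFA, which the ATF4 list also holds. ANGPTL4, another of the 8, had only 1.77 ± 0.771 CPM in neg and 0 reads in both pos libraries. The list's call ended without pos replicate 1 (adjusted p = 0.104, median -0.43) and was kept there with the length trend also removed.

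Genes of DNA replication and the cell cycle were higher in pos. Of 44 E2F targets 15 rose and none fell (26 rose when adjusted over the list alone), with a median of 0.81 and a camera adjusted p of 2.2e-11, or adjusted p = 0.345 with an estimated correlation. Thymidylate synthase (TYMS) rose by 2.14 on the log2 scale (SE 0.22), the dUTPase gene DUT by 1.62 (SE 0.22), RRM2 by 1.56 (SE 0.18) and the replication clamp gene PCNA by 1.52 (SE 0.21). PCNA was not past the threshold with the length trend removed (0.89, adjusted p = 0.116). Of 43 G2/M and mitosis genes 10 rose and none fell (14 rose when adjusted over the list alone). Their median was 0.52 and their camera adjusted p 6.6e-06, or adjusted p = 0.355 with an estimated correlation. Among them were the mitotic regulators BIRC5 (2.05, SE 0.24), CKS2 (2.09, SE 0.26), CCNB1 (1.38, SE 0.18) and CDC25C (1.73, SE 0.23). With the length trend removed the medians were 0.64 for E2F targets and 0.43 for G2/M genes, and with library size as the only scaling 0.39 and 0.14.

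Ribosomal protein and mitochondrial respiration genes, whose transcripts are short (median 1017 and 1191 nt), were higher in pos, and more so in pos replicate 3. Of 59 cytosolic ribosomal protein genes 17 rose and none fell (59 rose when adjusted over the list alone). Their median was 1.62 and their camera adjusted p 1.8e-21, or adjusted p = 0.447 with an estimated correlation. RPS3A rose from 1261 ± 96.7 to 5439 ± 2283 CPM and RPS18 from 3168 ± 354 to 14816 ± 9132 CPM. Of 47 nuclear genes for oxidative phosphorylation 25 rose and none fell (45 rose when adjusted over the list alone). Their median was 1.56 and their camera adjusted p 3.3e-20, or adjusted p = 0.355 with an estimated correlation. Examples were the complex I genes NDUFA9 (1.81, SE 0.27) and NDUFA4 (2.54, SE 0.38; 1.77 without pos replicate 3) and the ATP synthase gene ATP5F1 (1.41, SE 0.19). Of 38 mitochondrial ribosome and translation genes 13 rose and none fell (21 rose when adjusted over the list alone; median 0.91). The camera adjusted p was 5.7e-08, or adjusted p = 0.355 with an estimated correlation, and MRPL11 was at 2.24 (SE 0.35; 1.54 without pos replicate 3) and MRPL13 at 1.38 (SE 0.20; not past the threshold with the length trend removed, 0.67, adjusted p = 0.0517). Removing the length trend lowered the medians of the 3 lists to 0.60, 0.66 and 0.37, and without pos replicate 3 they were 0.80, 0.86 and 0.55.

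**Figure D3:**
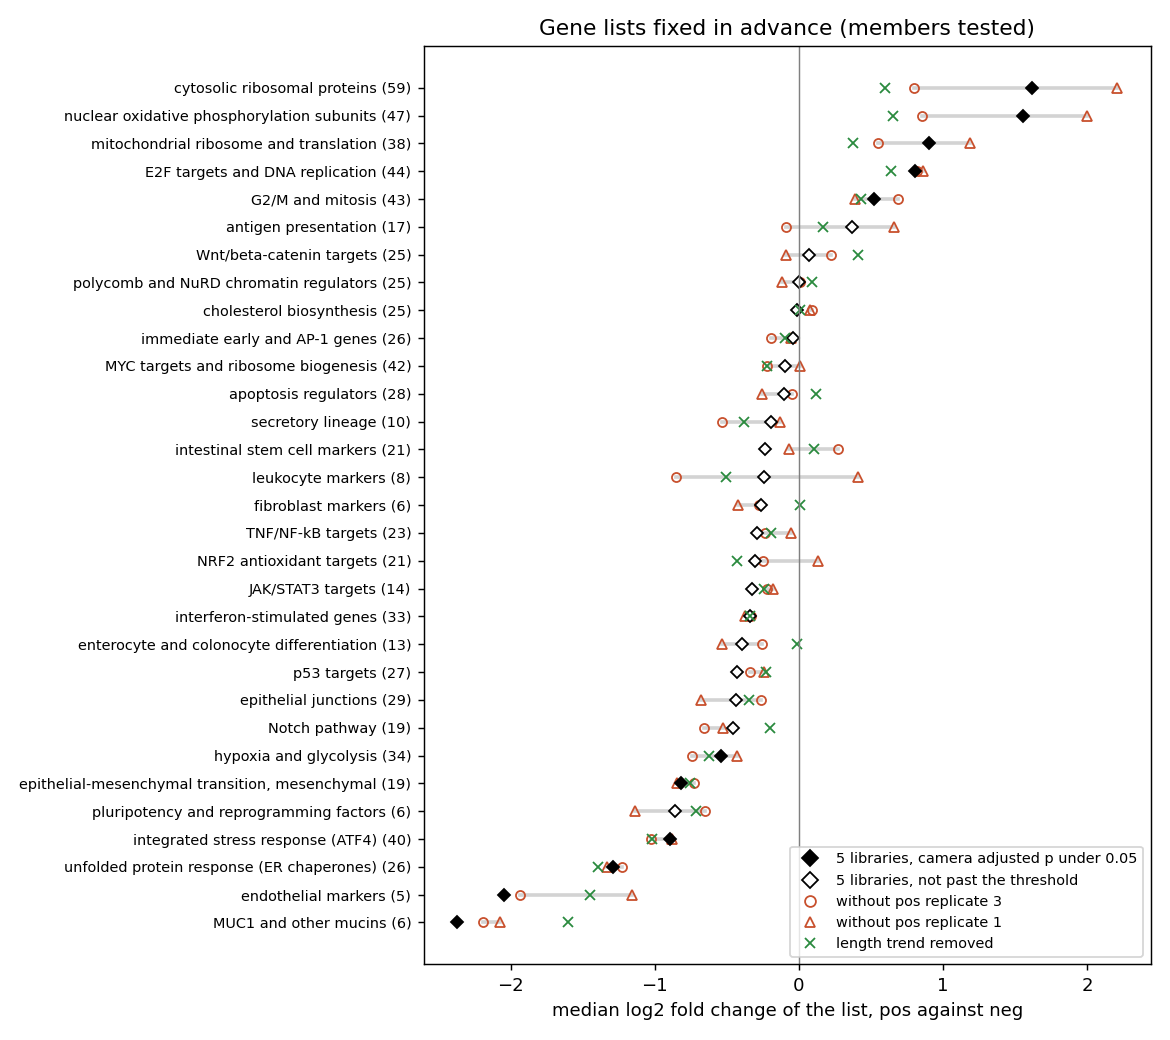
Median log2 fold change, pos against neg, of each of the 31 tested gene lists (number of tested members in brackets); diamonds use all 5 libraries and are filled where the camera adjusted p was under 0.05, circles leave out pos replicate 3, triangles leave out pos replicate 1 and crosses have the length trend removed. The ER chaperone (-1.29) and ATF4 (-0.89) lists lie at similar values in each fit, while cytosolic ribosomal proteins range from 0.60 with the length trend removed to 2.21 without pos replicate 1.

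Several intestinal stem cell and Wnt target genes rose, while the set tests of their lists did not pass the threshold. LGR5 rose by 2.28 on the log2 scale (SE 0.50, adjusted p = 0.0473), the Wnt-dependent stem cell factor ASCL2 by 1.91 (SE 0.42, adjusted p = 0.0457; 1.08 without pos replicate 3) and the stem cell marker SMOC2 by 1.25 (SE 0.22, adjusted p = 0.0382). These were the 3 of 21 tested intestinal stem cell markers past the threshold (4 higher and 1 lower when adjusted over the list alone). The list's test, which pointed up with a mean of 0.11 but a median of -0.23, did not pass (adjusted p = 0.648), and without pos replicate 1 it pointed down and did not pass. Among 25 Wnt targets LGR5, ASCL2, the secreted Wnt inhibitor NOTUM (1.46, SE 0.30) and APCDD1 (1.67, SE 0.17) rose and none fell (6 higher and 1 lower when adjusted over the list alone), at a list adjusted p of 0.223. The list tests passed in the upward direction with the length trend removed (adjusted p = 0.0400 for stem cell markers and 0.00108 for Wnt targets), and the Wnt list also without pos replicate 3 (adjusted p = 0.0129). Neither list passed with the length trend removed and an estimated correlation (adjusted p = 0.234 for both), nor did the stem cell list with the length trend removed and without pos replicate 1. The log2 fold change was 0.41 (SE 0.26) for AXIN2, -0.53 (SE 0.23) for CD44, -0.29 (SE 0.46) for PROM1, -0.37 (SE 0.81) for BMI1, -0.77 (SE 0.21) for MYC and -0.32 (SE 0.27) for SOX9, none past the threshold in edgeR on all 5 libraries. Without pos replicate 3 the log2 fold changes were 0.71 for AXIN2, -0.71 for CD44, -0.68 for MYC and -0.02 for SOX9. Without pos replicate 1 they were 0.04, -0.34, -0.83 and -0.70. PROM1 (0.27 and -1.27) and BMI1 (0.41 and -2.98) had opposite signs without pos replicates 3 and 1. BMI1 had 30 and 2 reads in pos replicates 1 and 3. AXIN2 (0.69, adjusted p = 0.0319) and MYC (-0.56, adjusted p = 0.0409) passed with the length trend removed. EZH2 was at 0.15 (SE 0.17), and at -0.24 with library size as the only scaling. MYC, with an adjusted p of 0.0660 in edgeR and 0.0149 in DESeq2, had 960 ± 75.8 CPM in neg and 565 ± 62.2 CPM in pos. OLFM4 and ALDH1A1 had too few reads to be tested, at most 1 and 10 in any library.

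Pluripotency and Notch genes went both ways. Of 6 tested pluripotency factors SOX2 rose 3.48-fold, and KLF4 fell by 2.17 on the log2 scale (SE 0.22). KLF5, named after its value was seen, fell by 1.85. Adjusted over the list alone, 3 were lower and 1 higher, and the list's adjusted p was 0.132. The list passed in the downward direction with fry (adjusted p = 0.0331) and with the length trend removed (adjusted p = 0.0400, or 0.234 with an estimated correlation), but not in that fit with pos replicate 1 or 3 left out. Of 19 Notch pathway genes the target gene HES1 rose by 1.89 (SE 0.43; 0.91 without pos replicate 3) and the receptor gene NOTCH3 fell from 3.47 ± 0.223 to 0.227 ± 0.0225 CPM, the latter from 3 and 2 reads. Adjusted over the list alone, 4 were lower and 1 higher (list adjusted p = 0.132). The Notch list passed in the downward direction with fry (adjusted p = 0.0103). It did not pass in camera with an estimated correlation (adjusted p = 0.355) or with the length trend removed (adjusted p = 0.240). Its median was -0.46, and -0.66 and -0.53 without pos replicates 3 and 1. NOTCH1 was at -1.45 (SE 0.35) with an adjusted p of 0.0544 in edgeR on all 5 libraries and 0.00153 in DESeq2, and at -0.68 (adjusted p = 0.0333) with the length trend removed. Among 13 enterocyte and colonocyte genes the colonic transcription factor gene CDX2 (2.18, SE 0.33; 1.56 without pos replicate 3) rose. Adjusted over the list alone, 3 were higher and 3 lower (list adjusted p = 0.928). The lysozyme gene LYZ (1.27, SE 0.23) was the only called gene of 10 in the secretory lineage, and with the length trend removed it did not pass (0.68, adjusted p = 0.0864). Adjusted over the list alone, 2 were higher and 2 lower, and the list had a median of -0.19 with a test pointing up (adjusted p = 0.973).

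Part of the mesenchymal genes and a few adhesion genes were lower. Of 19 mesenchymal genes 7 fell and 1, TGFBI (1.27, named after its value was seen), rose (10 fell and 3 rose when adjusted over the list alone). The median was -0.82 and the camera adjusted p 0.0107, or adjusted p = 0.355 with an estimated correlation. Tenascin C (TNC) fell by 1.98 (SE 0.28), COL6A2 by 1.52 (SE 0.22), COL1A1 by 1.36 (SE 0.21) and the integrin gene ITGA5 by 1.17 (SE 0.20). COL1A1 (-0.78, adjusted p = 0.0879) and ITGA5 (-0.83, adjusted p = 0.0539) were not past the threshold with the length trend removed. Of 29 epithelial junction genes E-cadherin (CDH1, -1.68, SE 0.34) and cingulin (CGN, -1.40, SE 0.24) fell and none rose (2 lower when adjusted over the list alone; list adjusted p = 0.118). The junction list passed in the downward direction with fry (adjusted p = 0.0209) and with the length trend removed (adjusted p = 0.0360, or 0.234 with an estimated correlation), but not in that fit without pos replicate 3. CDH1 had 522 ± 8.95 CPM in neg and 219 and 108 CPM in pos replicates 1 and 3. Of 6 tested mucin genes MUC1 and MUC3A (-2.36, SE 0.32) fell (4 when adjusted over the list alone), and MUC3A did not pass with the length trend removed (-1.40, adjusted p = 0.0929). The mucin median was -2.37 and the camera adjusted p 0.00110, or adjusted p = 0.355 with an estimated correlation. The mucin list holds MUC1, the target of the shRNA, and was not tested without it. Without pos replicate 1 the mesenchymal (adjusted p = 0.242) and mucin (adjusted p = 0.184) list calls ended, at medians of -0.85 and -2.07.

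The largest falls among genes at 5 CPM or more were in FLNC, which encodes the actin crosslinker filamin C (-5.42, SE 0.25, adjusted p = 0.00896), the glucose transporter gene SLC5A1 (-4.64, SE 0.39), the sodium channel gene SCN4A (-4.33, SE 0.42), LAMP3 (-4.12, SE 0.67), CREB5 (-4.09, SE 0.33), TIE1 (-4.03, SE 0.46), UNC5B (-4.01, SE 0.37), IGFBP1 (-4.01, SE 0.26), KRT16 (-3.98, SE 0.65) and BEST1 (-3.65, SE 0.65). FLNC went from 65.2 ± 4.66 to 1.52 ± 0.0884 CPM, the netrin receptor gene UNC5B from 188 ± 7.64 to 11.6 ± 5.68 CPM and the insulin-like growth factor binding protein gene IGFBP1 from 51.2 ± 6.56 to 3.18 ± 0.269 CPM. LAMP3 rested on 16 and 1 reads in pos replicates 1 and 3, KRT16 on 3 and 11, BEST1 on 4 and 20 and SLC5A1 on 12 and 4. In the same order SCN4A rested on 9 and 4 reads, TIE1 on 4 and 7, FLNC on 18 and 15 and CREB5 on 19 and 11. IGFBP1 had 37 and 32 reads and UNC5B 193 and 72. The largest rises were in BLOC1S1 (3.07), SPRYD4 (2.89), JAKMIP2-AS1 (2.89), ROMO1 (2.83), ATP5J2 (2.74), C6orf15 (2.72), DPM3 (2.69), NDUFA2 (2.64), RPS21 (2.62) and the metallothionein gene MT1E (2.60). With the length trend removed these ranged from 0.99 for RPS21 to 3.99 for SPRYD4, and BLOC1S1 stood at 1.54. Without pos replicate 3 they ranged from 1.31 for RPS21 to 2.72 for JAKMIP2-AS1. JAKMIP2-AS1 is an antisense transcript, and whether the counting used strand is not given in the sources used here.

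Markers of cells that a carcinoma line should lack were not all low, as COL1A1 had 16.2 ± 0.236 CPM in neg and LYZ 12.9 ± 1.62 CPM in pos. COL1A1 is also on the mesenchymal list and LYZ on the secretory lineage list, so these levels do not show that other cells were present. Of 5 tested endothelial markers TIE1 fell from 8.54 ± 1.75 to 0.531 ± 0.293 CPM and the other 4 were at 3.48 CPM or less in neg (4 fell when adjusted over the list alone). The median was -2.04 and the camera adjusted p 0.00190, or adjusted p = 0.355 with an estimated correlation. This call ended without pos replicate 1 (adjusted p = 0.345, median -1.16), and after leaving out neg replicate 2 or 3 the list was no longer tested. Of 6 fibroblast markers COL1A1 and COL6A3 were lower (2 when adjusted over the list alone; list adjusted p = 0.112, and 0.00520 with fry). COL6A3 had 5.08 ± 0.797 CPM in neg and 0 reads in both pos libraries. LYZ was the only called gene of 8 leukocyte markers (1 higher when adjusted over the list alone; list adjusted p = 0.664), and SERPINA1, the only tested gene of the erythroid and hepatocyte list, was at -0.62 (adjusted p = 0.115; 1 lower when adjusted over the list alone).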

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

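The fits that remove the length trend or weight libraries were chosen after the data were seen. MUC1 was lower in every setting run. Its log2 fold change ran from -3.42 to -2.82 with a library left out (-4.12 without pos replicate 1 and with the length trend removed), where the adjusted p was 0.178, 0.217 and 0.212 without neg replicates 1, 2 and 3, and it was -3.09 (adjusted p = 0.0786) with library quality weights. Its adjusted p over all settings ran from 4.8e-10 with DESeq2 to 0.217. The count of 1251 genes depended on the setting, and the causes were not tested. It was 606 with library size only, 3042 with DESeq2, 650 with glmTreat, 1 at an adjusted p under 0.01, 341 with library quality weights, 1888 with the length trend removed, and 3534 with the length and GC trend removed. With the length trend removed it was 4998 without pos replicate 3 and 7210 without pos replicate 1, and over single left-out libraries it ran from 0 (edgeR, without any neg replicate) to 8819 (without pos replicate 1). The other settings gave 1041 to 1334. The replicate block gave 87 (8 higher, 79 lower; 1669 at an unadjusted p under 0.05). The labels do not say that numbers mark a shared batch. Deviations from group means correlated at -0.44 for neg replicate 1 with pos replicate 1 and at -0.45 for the libraries numbered 3. With 2 pos libraries their deviations mirror each other, so these correlations cannot tell whether the numbers mark a shared batch. The 11 list calls were all kept with DESeq2 size factors, without a filter, under the replicate block and with fgsea (12 calls), 7 were among the 13 of fry (not ribosomal proteins, oxidative phosphorylation, mitochondrial ribosome or hypoxia, at adjusted p of 0.112, 0.0739, 0.0519 and 0.0519), and 8 to 13 lists were called with a library left out. With the length trend removed 18 lists were called, 20 with GC too, 19 without pos replicate 3 and 9 without pos replicate 1, where the G2/M list also lost its call (adjusted p = 0.0668). An estimated correlation left 0 camera calls with the trend (3 lists at an unadjusted p under 0.05) and 0 with it removed (4 lists). That form of the test also uses only the residual degrees of freedom of the 5 libraries. Of the 92 other genes followed, only B2M changed sign among those called in the main analysis, from 1.13 to -0.12 with the length trend removed and without pos replicate 1. Of 100 simulated 2-fold changes 2 were recovered at the spread of the main fit and 27 at the spread left after removal of the length trend.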

Other observations

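All tests of explanations below were chosen after the patterns were seen.

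Some p53, NRF2 and AP-1 target genes differed between pos and neg. Of 27 p53 targets SESN2, also on the ATF4 list, and the death receptor gene TNFRSF10B (-1.45, SE 0.19) fell. CDKN1A (-1.98) and EDA2R (2.36 ± 0.694 CPM in neg and 0 reads in both pos libraries) also fell, and TP53I3 (2.15) rose. The last 3 were named after their values were seen, and adjusted over the list alone 4 were lower and 4 higher (list adjusted p = 0.138). Of 21 NRF2 antioxidant targets the haem oxygenase gene HMOX1 fell by 2.22 on the log2 scale (SE 0.32) and SRXN1 from 122 ± 9.71 to 61.7 ± 0.408 CPM, while PGD (0.94, named after its value was seen) rose (3 lower and 1 higher when adjusted over the list alone; list adjusted p = 0.540). Of 26 immediate early and AP-1 genes FOSL2 (-2.05, SE 0.35), the phosphatase gene DUSP5 (-0.97, SE 0.20) and ATF3 (-1.36, also on the ATF4 list, named after its value was seen) fell and none rose (7 lower when adjusted over the list alone; list adjusted p = 0.283). With the length trend removed these 3 lists passed in the downward direction, at adjusted p of 0.0222, 0.00821 and 0.0237, which was 0.234 for each with an estimated correlation, and none passed in that fit without pos replicate 1. The p53 and AP-1 lists also passed with fry (adjusted p = 0.0127 and 0.0289), and the AP-1 list with fgsea (adjusted p = 0.00860).

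Of 17 antigen presentation genes PSMB8 (1.91, SE 0.38; 1.17 without pos replicate 3) and B2M (1.13, SE 0.19) rose and NLRC5 (-1.83, named after its value was seen) fell (4 higher and 3 lower when adjusted over the list alone; list adjusted p = 0.259, and 0.0449 in the upward direction without pos replicate 1), and the list median of 0.37 was -0.12 with library size as the only scaling. B2M did not pass with the length trend removed (0.20, adjusted p = 0.556). The protease gene PLAU (-1.21, SE 0.26) was the only called gene of 23 TNF and NF-kB targets and GBP2 (-1.47, SE 0.30) of 33 interferon-stimulated genes, where GBP2 did not pass with the length trend removed (-1.18, adjusted p = 0.0629). Each of these lists had 0 genes when adjusted over the list alone, with list adjusted p of 0.584 and 0.383, and so did 25 polycomb and NuRD genes (list adjusted p = 0.957). The interferon list passed in the downward direction with the length and GC trend removed (adjusted p = 0.0424). With the length trend alone removed it did not pass (camera adjusted p = 0.0511, or 0.234 with an estimated correlation). Of 42 MYC target and ribosome biogenesis genes RRP12 (-1.10, SE 0.21) and MYBBP1A (-0.92, SE 0.20) fell and POLR1C, named after its value was seen, rose (0 when adjusted over the list alone; list adjusted p = 0.701). RRP12 (-0.72, adjusted p = 0.110), MYBBP1A (-0.55, adjusted p = 0.112) and POLR1C did not pass with the length trend removed. The MYC target list passed in the downward direction with the length and GC trend removed (camera adjusted p = 0.0281). With the length trend alone removed that list did not pass (adjusted p = 0.0549, or 0.234 with an estimated correlation). ACAT2 (0.97, SE 0.19) was the only called gene of 25 in cholesterol biosynthesis (0 when adjusted over the list alone; median -0.01 and mean 0.14, adjusted p = 0.498), and it did not pass with the length trend removed (0.40, adjusted p = 0.187). No gene of 14 JAK/STAT3 targets passed either adjustment (list adjusted p = 0.540). Of 28 apoptosis regulators BIRC5 and CASP6 (1.13, named after its value was seen) rose and TNFRSF10B fell (3 higher and 3 lower when adjusted over the list alone; median -0.10, test direction up, adjusted p = 0.957), and CASP6 did not pass with the length trend removed (0.66, adjusted p = 0.155).

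ER chaperone and ATF4 genes were lower in both pos libraries. The length trend is argued against as the whole cause, since the median of the 66 members was -1.10 with the trend removed, and so is a loss of low counts, since the 57 members above 50 CPM in neg had a median of -0.95. If pos stands for doxycycline, MUC1 silencing, a drug effect and a difference in culture state such as nutrient supply cannot be told apart. That is because 0 doxycycline-treated libraries without the MUC1 shRNA were analysed. A fall in stress signalling after MUC1 loss is therefore only a hypothesis. A control shRNA with doxycycline would separate it from an effect of the drug only.

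Short transcripts were higher in pos, with a Spearman rho of log2 fold change and transcript length of -0.58 across genes. A rise of ribosomal protein and mitochondrial genes alone is argued against, because rho was -0.57 across the 12895 genes left without them. A length trend that differs between single libraries is consistent with the slope of pos replicate 3 against pos replicate 1, 2 libraries of the same group, of -0.55 log2 units per doubling of length, when neg libraries differed by at most 0.14. Part of the rise of ribosomal protein and oxidative phosphorylation genes may therefore come from the libraries, and a group effect on short transcripts stays open, since pos replicate 1 had a slope of -0.19 against neg.

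Fewer genes were detected in pos at similar depth. Lower depth is argued against, as pos replicate 1 had 12190025 counts, inside the neg range of 10888704 to 14137678. Reads copied from few molecules would remove genes with exactly 1 read, and pos replicate 1 had 143 of them and pos replicate 3 had 580, against at least 1118 in neg. Among genes for which the neg libraries scaled to its depth gave 3 to 6 reads, 55.5% were at 0 in pos replicate 1 (4.64% to 7.16% in neg libraries treated alike), yet the detected ones had a median of 7 reads against 4 in each neg library, which argues against loss of expression of low genes as the whole cause there. In pos replicate 3, with 33.1% at 0 and a median of 4 reads, loss of expression stays open beside copied reads. If all zeros came from copied reads, these shares would give 6.58 and 3.13 reads per independent read in pos replicates 1 and 3, against 1.47 to 1.58 in neg. Zeros and low counts in pos, such as those of COL6A3, TIE1, NOTCH3 and MUC1, may therefore carry more error than counting intervals show. The same holds for rises on few reads, such as that of LGR5 (218 and 58 reads in pos replicates 1 and 3).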
